A study of Homo sapiens with 77 samples.

How the data were processed

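ChIP-seq peak lists of 4 MCF-7 libraries were analysed: HEXIM1 and KAP1, each with ethanol and with 100 nM 17β-estradiol for 40 min. Groups were taken from the sample titles. The series has 77 samples in 51 groups, with 4 samples of HEXIM1 and 6 of KAP1, and 4 samples entered the analysis. The other samples, which cover histone marks, RNA polymerase II and other factors, were not analysed here.

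The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, HOMER and hg38, and versions are not given in the sources used here. Per the file headers, peaks were called with HOMER findPeaks in factor mode with centring, once per library and not on pooled samples, and the commands in the headers name no control library. Per the file headers, a peak had to pass a false discovery rate of 0.001, 4-fold over the local 10 kb and a local Poisson p-value of 1e-04, and tags were scaled by the authors to 10000000 per library. The signal used for heights is this deposited tag count, in tags per 10M. The other deposited columns are the focus ratio (a fraction of tags on the expected side of the centre), the caller's score, the ratio or fold over the local region, a clonal ratio and the p-value against the local region; of these the authors' fold was used to filter and divide peaks within a list, and the score, fraction and p-value columns were read only to check their ranges. The score and fold belong to the authors. Per the file headers, total tags were 65425368 and 79830019 for HEXIM1 (vehicle and estradiol) and 61264298 and 65374891 for KAP1. The approximate enrichment efficiencies there were 1.22%, 0.30%, 0.77% and 0.56%, which equal the tags in called peaks as a share of total tags. The headers give tag thresholds of 25, 26, 25 and 27 for a peak, or 3.82, 3.26, 4.08 and 4.13 normalised tags, so this limit was of similar size in the 4 lists. Of the 51128, 48985, 72376 and 64180 putative peaks, 71.0%, 89.7%, 88.6% and 90.8% were removed by the local filter. Peaks were 247, 222, 279 and 295 bp wide by the headers, and those of the HEXIM1 estradiol list span 1 bp more in the file, so a tag count covers slightly different widths; an alternative divides by width.

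Everything after the peak lists was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Peaks on chromosomes 1 to 22, X and Y were used. Peaks were called shared if they overlapped by at least 1 bp, and each was paired with the peak of closest centre. Counts differ slightly with the direction of an overlap, since 1 peak can meet several. Shares have exact (Clopper-Pearson) binomial intervals at 95%. Each overlap was set beside 1000 random placements of the peaks on their chromosomes and, for boundary peaks, 200 placements on random gene boundaries. Tags per peak were turned back into whole tags with the library total, and heights have exact Poisson intervals and ratios exact conditional binomial intervals at 95%. PCR copies are not independent molecules, so these intervals cover counting error only. Ratios of tags were taken only at peaks in both lists.

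Gene positions came from a RefSeq table of GRCh38.p14 with 20037 protein-coding symbols, which has gene ends but no strand, transcripts or sequence. The design written before the data were examined asked for transcription starts. In their place a peak was counted as a gene boundary peak if its centre lay within 1 kb of either end of a protein-coding gene, so that 3′ ends are included and promoters cannot be told from them. A search for estrogen response elements, the match of random lists on promoter CpG content and the variant with 1 start per gene need a genome or strand and were not run. Gene-free bins are 1 Mb bins that overlap no protein-coding gene. They were introduced after the data were seen, as were the separation of peaks that are also in a list of the other protein and the class of strong peaks (at least 8-fold, away from boundaries, in neither list of the other protein).

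The 12 gene lists were fixed before the data were examined: early estrogen-responsive genes, immediate early and stress genes, P-TEFb, 7SK and pausing factors, KAP1 and heterochromatin proteins, chromosome 19 zinc finger genes, ribosomal protein genes, replication-dependent histone genes, clustered protocadherins, imprinted genes, markers of other cell types, olfactory receptors and small nuclear RNA genes. One symbol was matched by its current name, NHERF1. All symbols matched except 3 of the 22 imprinted genes, which are not protein-coding in the table. The percentile of a list is its place among 10000 random lists of the same size from protein-coding genes. Peaks within genes and near genes were compared with lists matched on 5 classes of gene length, and genes with a peak in both conditions with genes matched on 5 classes of vehicle tags or of vehicle fold. Percentiles describe these libraries and are no test of the conditions. Small nuclear RNA genes have no percentile.

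Genes were named by a rule written before the data were examined. For each protein it takes, among gene boundary peaks by nearest gene, the 10 highest called in both conditions by the mean of both, the 5 highest called only with vehicle, the 5 highest called only with estradiol, the 3 highest and 3 lowest ratios with at least 30 normalised tags in either condition, and the highest members of each list, and among other peaks the 5 highest per list. Genes near the strong peaks, small nuclear RNA genes with an estradiol peak and further estrogen-responsive genes were named after their values were seen.

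The computations were tested on simulated peaks. With 30% of 14833 HEXIM1 peaks planted in a second list, 30.1% were recovered, and with 8278 KAP1 peaks 30.0%. A planted log2 ratio of −0.74 at 3164 HEXIM1 peaks was recovered as −0.74. This simulation did not apply the caller's limits. It therefore cannot show how the ratios shift because only peaks called in both lists have one. The alternatives were other overlap rules, other windows, lists of equal length, an 8-fold limit, all contigs and removal of crowded 1 Mb bins, all planned, and removal of gene-free bins, of peaks shared with the other protein and of the width difference, which were added later.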

Results

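Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used in MCF-7 cells, an estrogen receptor-positive human breast cancer line, to map 2 regulators of transcription elongation. HEXIM1 holds the elongation kinase P-TEFb inactive within the 7SK small nuclear ribonucleoprotein. KAP1 (TRIM28) is a corepressor recruited by KRAB zinc finger proteins that is also known to bring the 7SK complex to promoters. Cells grown in charcoal-stripped serum received 100 nM 17β-estradiol for 40 min or ethanol (vehicle). Of the 77 samples of the series, 4 were analysed here, 1 per protein and condition, and the other samples were not analysed here. The libraries held 65425368 tags for HEXIM1 with vehicle, 79830019 for HEXIM1 with estradiol, 61264298 for KAP1 with vehicle and 65374891 for KAP1 with estradiol. With 1 library per condition there is no replicate error, no test between conditions was possible, and the 95% intervals given cover counting error only. Heights are given as normalised tags, the authors' tag counts scaled to 10000000 tags per library. The headers name no control library, so an order by height is not an order by enrichment. All positions are in hg38. Gene boundaries are the annotated ends of protein-coding genes, start and stop alike, because the gene table used here gives no strand.

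The first comparison asked where HEXIM1 was found with and without a short estradiol pulse. Called HEXIM1 peaks at gene boundaries were fewer and lower with estradiol. The list held 14833 peaks with vehicle, of which 6575 lay within 1 kb of a gene boundary, and 5027 with estradiol, of which 1577 did. Before the local filter there were 51128 and 48985 putative peaks at all locations. The difference in number thus arose mostly at the limit of 4-fold over the local 10 kb and its p-value, not at the tag threshold. At protein-coding genes, 7478 had a boundary peak with vehicle and 1808 with estradiol, and 1577 genes had one in both. At the 1103 boundary peaks called in both lists, the median estradiol/vehicle ratio of tags was 0.604 (log2 −0.73, quartiles −0.95 and −0.52), and 1092 of them held fewer tags with estradiol. In contrast, the 1247 shared peaks in 1 Mb bins without any protein-coding gene had a median log2 ratio of −0.042. Peaks of the estradiol list were narrower, and divided by peak width these medians were −0.58 at boundaries and 0.11 in the gene-free bins. Over all 3164 shared vehicle peaks the median was −0.29, and it was −0.64 without the gene-free bins. Of the vehicle boundary peaks, 5472 were not called with estradiol and have no ratio. The medians thus describe only peaks that passed the caller's limits in both libraries.

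The 10 HEXIM1 boundary peaks called in both lists with the highest mean of both conditions were all lower with estradiol, to very different extents. At CAP2, a regulator of actin (gene 10486, chromosome 6, 17393818 to 17394064, inside the gene), normalised tags were 64.5 (95% interval 58.5 to 71.0) with vehicle and 6.39 (4.76 to 8.40) with estradiol. ADAMTSL5 (chromosome 19, 1513224 to 1513470) had 47.7 and 4.76, THSD4 43.9 and 5.14, CHPT1 53.5 and 7.39, and the predicted gene LOC124904102 79.8 and 8.27. Others kept a larger part. The highest ratio among boundary peaks with at least 30 normalised tags was at the peak at 52995715 to 52995961 on chromosome 6, next to GSTA4 (gene 2941) and over RN7SK (52995620 to 52995951), the gene of the 7SK RNA that HEXIM1 binds, with 31.0 (26.9 to 35.6) and 21.0 (18.0 to 24.5) and a log2 ratio of −0.56 (−0.86 to −0.26). DTWD1 had 33.2 and 18.2, PRKAB2, a subunit of AMP-activated kinase, 29.0 and 18.8, POLR2J3 27.7 and 14.2, and ARFGEF2 25.5 and 15.5. Outside these 10, DMRT2 had 35.2 and 5.26.

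The highest boundary peaks called only with vehicle were at IL24 (71.8 normalised tags), WDR45B (53.3), NHERF1 (45.5), TFF1 (41.9) and DECR1 (41.4). By fold over the local 10 kb, WDR45B was the highest of these 5 (28.8), IL24 had 15.5 and TFF1 was the lowest (14.8). The 5 highest boundary peaks called only with estradiol were lower and all under 5-fold, near the 4-fold limit of the caller. They were at XBP1 (9.65, 4.10-fold), ZHX1-C8orf76 (9.02), DSTYK and ELK4 (7.77 each) and PDXDC1 (7.64). Of the 1864 HEXIM1 peaks called only with estradiol, 71.2% were under 5-fold over the local 10 kb, and of the 11669 called only with vehicle 41.6%.

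Of all HEXIM1 vehicle peaks, 21.3% (95% exact binomial interval 20.7 to 22) overlapped an estradiol peak, and 62.9% (61.6 to 64.3) of the estradiol peaks overlapped a vehicle peak. These shares depend on the lengths of the lists: among equal numbers of the strongest peaks, both were 24.2% (23 to 25.4). Random placements on the same chromosomes gave at most 0.175% and 0.517%. Peaks at gene boundaries made up 44.3% (43.5 to 45.1) of the vehicle list and 31.4% (30.1 to 32.7) of the estradiol list, against 2.86% and 2.87% at random positions. This order of the shares turned without the gene-free bins, which held 11.6% of the vehicle and 41.3% of the estradiol peaks: the shares were then 50.1% and 53.5%. Among peaks of at least 8-fold they were 15.7% and 8.20%.

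**Figure D1:**
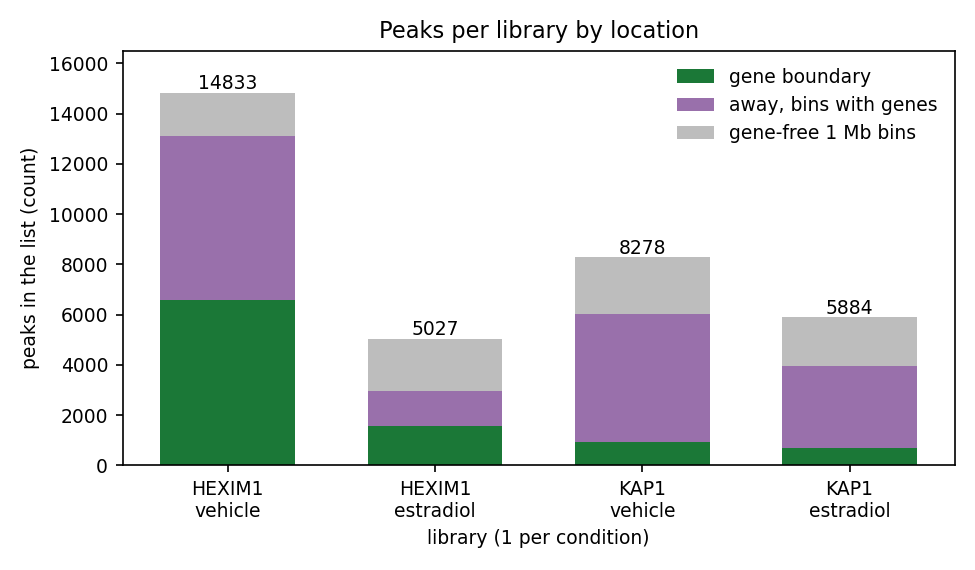
Number of peaks in each of the 4 lists (bars, 1 library per condition), divided by location: within 1 kb of a protein-coding gene boundary, away from boundaries in 1 Mb bins that hold a gene, and in gene-free bins. HEXIM1 had 6575 boundary peaks with vehicle and 1577 with estradiol, whereas its peaks in gene-free bins numbered 1715 and 2077.

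**Figure D2:**
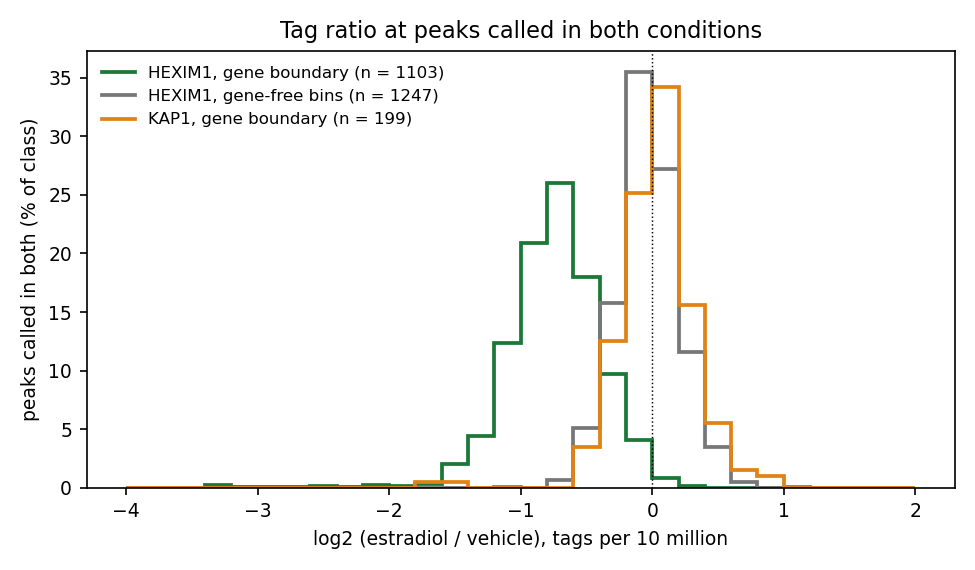
Distribution of the log2 estradiol/vehicle ratio of normalised tags at peaks called in both conditions, as the percent of each class. HEXIM1 boundary peaks centre on −0.73, HEXIM1 peaks in gene-free bins on −0.042 and KAP1 boundary peaks on 0.048.

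Gene lists fixed before the data were examined were unevenly represented in the HEXIM1 vehicle library. The random lists were not matched on promoter CpG content or on gene activity. The percentiles therefore do not show a preference of HEXIM1 for a list beyond these traits. Components of P-TEFb, the 7SK particle and the pausing machinery had a boundary peak in 16 of 20 genes (percentile 100 among 10000 random lists, median 7). AFF1, a scaffold of the super elongation complex, had 24.6 normalised tags (21.0 to 28.7), POLR2A, the largest subunit of RNA polymerase II, 15.3, and NELFB, a subunit of the pausing factor NELF, 12.8. Ribosomal protein genes had one in 69 of 86 genes (random median 32, percentile 100), led by RPL27 (15.1) and RPLP0 (14.1). Genes of heterochromatin proteins had one in 13 of 19 (random median 7, percentile 99.8), with TRIM28 itself at 10.7 and CBX3 at 9.32. Replication-dependent histone genes had one in 32 of 68 (percentile 94.8), led by H4C14 (20) and H4C15 (18.3), and immediate early and stress genes in 16 of 33 (percentile 90.4), led by ZFP36 (14.4) and IER5 (13.8). Of 42 small nuclear RNA genes 21 had one, with RNU1-1 at 17.4. Chromosome 19 zinc finger genes (89 of 240) were close to random lists. So were early estrogen-responsive genes within 1 kb (14 of 40, percentile 39.5), whereas within 5 kb they lay near the upper end of random lists (24 of 40, random median 18, percentile 97.2). Olfactory receptor genes (0 of 390), clustered protocadherin genes (0 of 53), imprinted genes (1 of 19, MEST) and markers of other cell types (2 of 32, with APOA1 at 33.3) were at the bottom.

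With estradiol, none of the 32 histone genes with a HEXIM1 vehicle peak had a peak, against a median of 9 in random genes matched on vehicle tags and 6 in genes matched on fold (percentiles 0 and 0.0300). Of the ribosomal protein genes 9 of 69 had one in both, against 17 and 15 (percentiles 0.640 and 4.47), and of the zinc finger genes 10 of 89, against 14 and 18 (11.7 and 0.875), so that these lists lay below the middle 95% of random genes with 1 of the matchings and within it with the other. Of the immediate early genes 1 of 16 did, GADD45A, against 4 and 3 (2.95 and 7.94), of the early estrogen-responsive genes 1 of 14, against 3 and 3 (6.45 and 11.4), of the pausing factors 5 of 16, against 4 and 3 (71.9 and 86), and of the heterochromatin genes 3 of 13, against 3 and 2 (58.3 and 71.8). In the estradiol list as a whole, boundary peaks were at 5 pausing factors (percentile 98.4), 3 heterochromatin genes, 10 ribosomal protein genes, 11 zinc finger genes (percentile 0.450), 5 early estrogen-responsive genes (7 of 40 had a peak within the gene, percentile 99.0 among length-matched lists, and 16 with vehicle, percentile 92.3), 1 immediate early gene and 1 marker of another cell type, and at 0 histone, protocadherin, imprinted and olfactory receptor genes. RN7SK and 3 U1 or U1-variant genes, RNU1-2, RNVU1-18 and RNVU1-27, were the small nuclear RNA genes with a peak in the estradiol list. These 3 U1 or U1-variant genes also had a KAP1 peak in both conditions (RNVU1-27 15.7 and 11.6), whereas RN7SK had none. Their HEXIM1 peaks are therefore not particular to HEXIM1. Neighbouring histone genes share peaks, so these genes are not independent.

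Among the early estrogen-responsive genes, the HEXIM1 peaks within 1 kb of a boundary at TFF1, a secreted trefoil peptide (gene 7031, chromosome 21, 42366593 to 42366839, 181 bp outside the gene, 41.9 normalised tags, 37.1 to 47.1), NHERF1 (45.5, 40.5 to 51.0), PDZK1 (34.2), CCND1, which encodes cyclin D1 (12.1), SIAH2 (11.6) and GREB1 (6.88) were called with vehicle and not with estradiol. IGFBP4 had a boundary peak in both lists (11.8 and 7.14). XBP1, MYB (4.38), SGK3 (3.76) and TPD52L1 (3.63) had a boundary peak only with estradiol, but each also had a higher peak called only with vehicle farther from its boundary, with 35.6 and 6.57 normalised tags outside XBP1 and MYB and 16.7 and 26.4 inside SGK3 and TPD52L1. A list says nothing of the tags at a site it does not hold, beyond that the site did not pass the caller's limits.

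Strong HEXIM1 vehicle peaks away from gene boundaries and outside the KAP1 lists were seldom called with estradiol. This class, the removal of peaks in the KAP1 lists included, was chosen after the data were seen. Of 1576 vehicle peaks that were at least 8-fold over the local 10 kb, away from boundaries and in neither KAP1 list, 70 (4.44%, 3.48 to 5.58) overlapped an estradiol peak, compared with 97 of 319 such peaks at boundaries (30.4%, 25.4 to 35.8), although the peaks away from boundaries held more tags (median 13.3 against 9.17 normalised tags). With the peaks in the KAP1 lists the difference was smaller, 522 of 2089 (25%, 23.1 to 26.9) away from boundaries against 145 of 390 (37.2%, 32.4 to 42.2) at boundaries. In neither KAP1 list the order turned only among the weakest peaks. From 4-fold to below 5-fold, 12.0% (10.7 to 13.3) were kept away from boundaries and 8.77% (7.68 to 9.95) at boundaries. From 6-fold to below 8-fold the shares were 10.9% (9.14 to 12.9) and 20.1% (17.9 to 22.4), and over all peaks below 8-fold 12.6% and 13.2%. Over all folds they were 10.6% (9.86 to 11.4) and 14.1% (13.2 to 15.0). With the peaks in the KAP1 lists, they were 25% (24.0 to 25.9) and 16.8% (15.9 to 17.7) over all vehicle peaks. Of the early estrogen-responsive genes, 29 of 40 (72.5%, 56.1 to 85.4) lay within 100 kb of one of the 1506 strong peaks called only with vehicle. This compares with a median of 5 in random lists matched on gene length, not on gene activity, and 13.0% of all genes. From 15-fold 14 of 40 (35%, 20.6 to 51.7) did. Some neighbours share a peak, such as TFF1 and TFF3, so that the highest peak per gene gave 26 distinct peaks. Of the 1506, the highest within 100 kb of a gene boundary were nearest to IGBP1C (73.8) and CTBP1 (70.3), and the 10 highest included peaks nearest to PREX1 (57.5), IL19 (56.9), TP63 (55.6), HES1 (54.1) and NAIF1 (53.5), none of which is in that list. Of the list, GREB1, an estrogen-induced gene (gene 9687), held 4 of the 1506, the highest at 11539629 to 11539875 on chromosome 2, 56.9 kb inside the gene, with 60.1 normalised tags (54.3 to 66.3, 39.3-fold). Another GREB1 peak at 11498590 to 11498836 was called in both lists, with 46.6 and 5.01. Others lay outside SMAD7, an inhibitor of TGF-β signalling (chromosome 18, 48990909 to 48991155, 64.5), outside SIAH2, a ubiquitin ligase (chromosome 3, 150737305 to 150737551, 58.5), inside TMPRSS3 at 9.95 kb from TFF1 (chromosome 21, 42376362 to 42376608, 51.7), inside IGFBP4 (chromosome 17, 40448719 to 40448965, 46.2), and near XBP1 (35.6), MYC (35.8) and PGR (14.8, inside the gene). Of the other lists, only the histone genes lay well above matched random lists (15 of 68, median 7). Neighbouring histone genes can share a peak, and distinct peaks were not counted for them. No strong KAP1 peak away from boundaries and in neither HEXIM1 list lay within 100 kb of an early estrogen-responsive gene in either condition. The KAP1 sets held 401 and 162 peaks, but random lists gave medians of only 1 and 0 (percentiles 11.5 and 26.9).

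**Figure D3:**
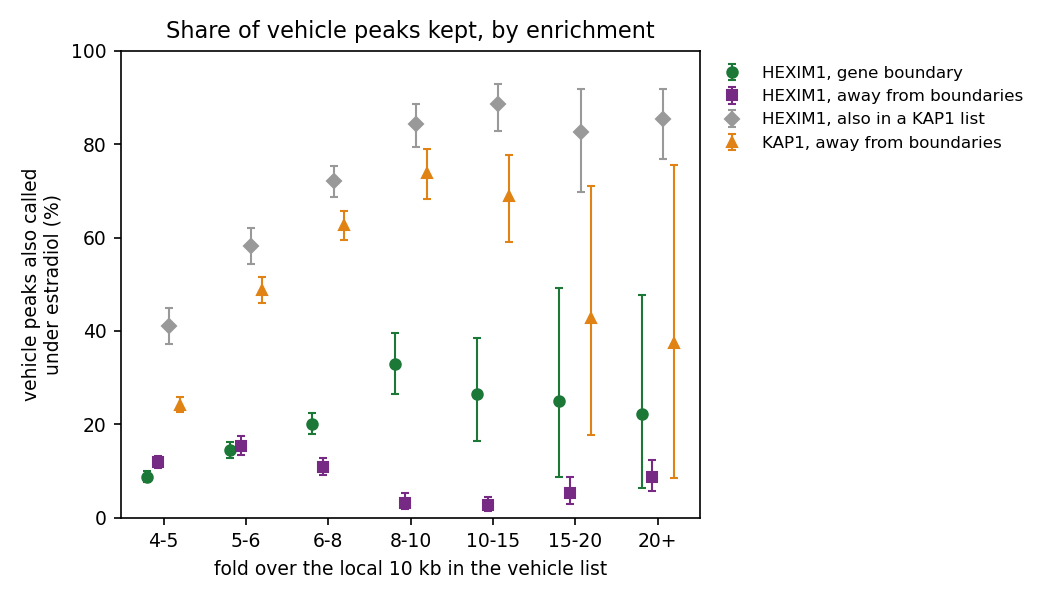
Percent of vehicle peaks that overlapped an estradiol peak (vertical axis) by fold over the local 10 kb in the vehicle list (horizontal axis), with 95% exact binomial intervals as bars. From 8-fold upward, HEXIM1 peaks at boundaries in neither KAP1 list were kept in 30.4% and those away from boundaries in 4.44%, whereas HEXIM1 peaks that were also in a KAP1 list were kept in 85.6% and KAP1 peaks away from boundaries and in neither HEXIM1 list in 70.8%.

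**Figure D4:**
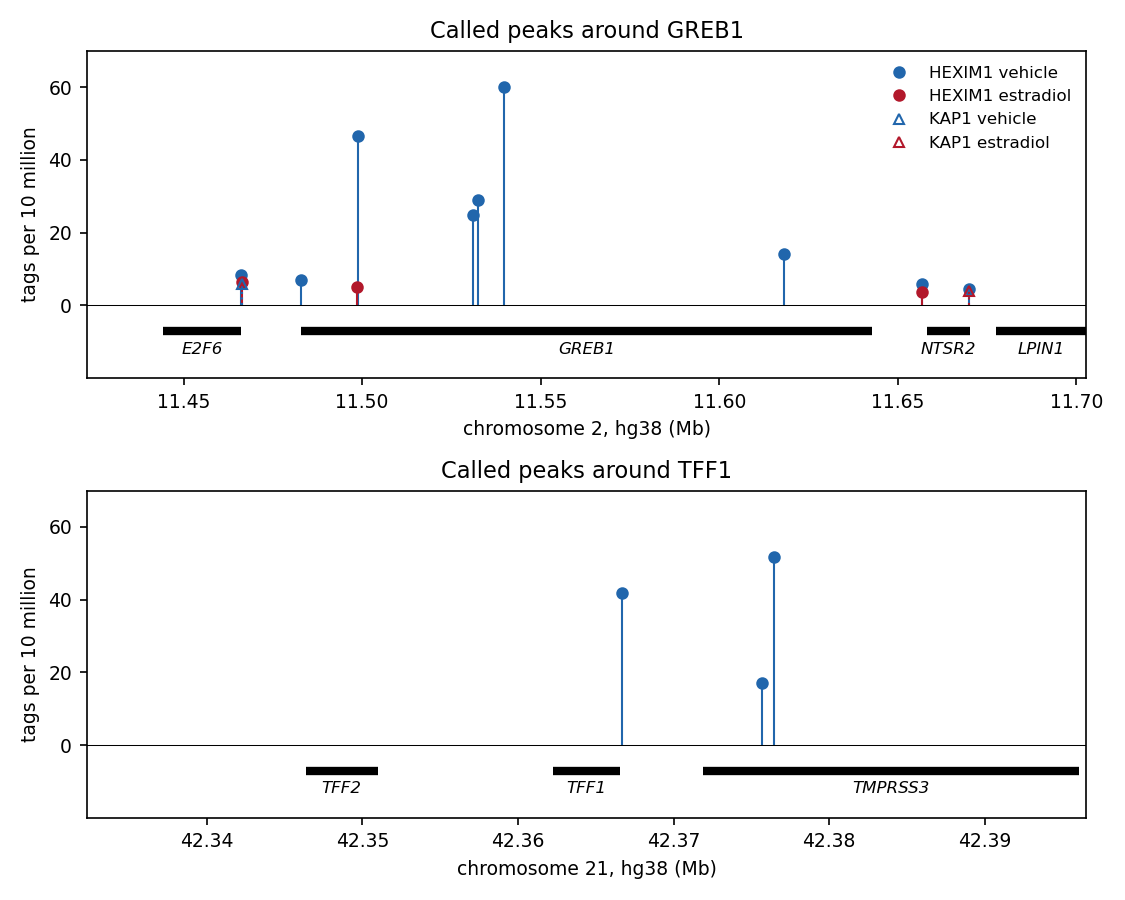
Called peaks around GREB1 on chromosome 2 and TFF1 on chromosome 21 (hg38 position in Mb) with their height in tags per 10M; filled circles are HEXIM1, open triangles KAP1, blue vehicle, red estradiol, and black bars genes. The HEXIM1 vehicle peaks inside GREB1 reach 60.1, and the peak called there in both lists has 46.6 with vehicle and 5.01 with estradiol.

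The second comparison asked the same of KAP1, whose peaks lay mostly away from gene boundaries and were over the whole lists more often called in both conditions. The list held 8278 peaks with vehicle and 5884 with estradiol. Of the vehicle peaks 47.0% (45.9 to 48.0) overlapped an estradiol peak, and of the estradiol peaks 66.1% (64.8 to 67.3) overlapped a vehicle peak, against at most 0.290% and 0.408% at random. This order of the proteins turned in some classes: of the estradiol peaks at boundaries 28.9% (25.5 to 32.4) of KAP1 and 69.7% (67.4 to 72.0) of HEXIM1 overlapped a vehicle peak, of those outside the gene-free bins 60.7% (59.1 to 62.2) and 64.9% (63.2 to 66.7), and of the vehicle peaks in those bins 66.1% (64.1 to 68.0) and 72.7% (70.5 to 74.8) overlapped an estradiol peak. Gene boundaries held 11.4% (10.7 to 12.1) and 11.7% (10.8 to 12.5) of the peaks, shares that differed by less than their intervals, and 2.86% and 1.44% of the peaks of at least 8-fold. Over 100 kb from any gene boundary lay 44.4% and 48.2%. The median log2 ratio of tags at the 3887 shared peaks was −0.15, and at the 199 shared boundary peaks 0.048, which became −0.032 when divided by peak width.

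By the mean of both conditions, the highest KAP1 boundary peak called in both lists was at RAE1, a factor of messenger RNA export (gene 8480, chromosome 20, 57350799 to 57351077, 317 bp outside the gene), with 35.3 normalised tags (30.7 to 40.3) with vehicle and 10.2 (7.94 to 13.0) with estradiol, a log2 ratio of −1.79 (−2.20 to −1.38). It was the only shared boundary peak of KAP1 with at least 30 normalised tags. LOC124901807 (22 and 21.1) was next, followed by KCNJ15, a potassium channel, with 22.7 and 17.1 (log2 −0.41, −0.78 to −0.036). For the 10 highest except RAE1 and KCNJ15 the interval of the log2 ratio included 0, among them LOC124901807, CEP15 (16.5 and 17.9), PUS7, a pseudouridine synthase (15.0 and 16.1), ZNF783, a KRAB zinc finger gene (15.5 and 14.5), and KMT2A, a histone H3 lysine 4 methyltransferase (11.8 and 12.2). ATXN7L1, TSPAN15 and STX16 had 11.4, 11.6 and 11.1 with vehicle. Called only with vehicle were peaks at UBB, which encodes ubiquitin (18.3), POLR2J3 (17.3), MYO5A (16.8), H2AZ1, which encodes a histone variant (14.7), and LOC124904903 (13.7). Called only with estradiol were SMARCD2, a subunit of the SWI/SNF remodelling complex (13.5), DDX59 (12.4), RTEL1 (12.2), APRT (11.9) and FAM91A1 (11.3). Of the 1997 KAP1 peaks called only with estradiol, 77.5% were under 5-fold, and of the 4391 called only with vehicle 67.2%.

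Few genes of the fixed lists had a KAP1 peak within 1 kb of a boundary. Of the chromosome 19 zinc finger genes, textbook KAP1 targets, 7 of 240 had one with vehicle and 6 with estradiol, with ZNF875 highest (10.8 and 9.94), followed by ZNF77 (8.98 and 6.88), and 16 and 10 had a peak within the gene (percentiles 19.5 and 18.6 among lists matched on gene length). Ribosomal protein genes had a peak within the gene in 18 of 86 with vehicle, above the length-matched lists (percentile 100), and in 0 with estradiol (percentile 6.07). At their boundaries 8 and 3 had one, with RPL10L (13.7) and RPL30 (8.98) highest, and within 5 kb 20 and 3 (percentiles 100 and 14.9 among random lists). CDK9, the kinase of P-TEFb, had KAP1 boundary peaks in both conditions (5.88 and 7.80), as did AFF1 (4.90 and 5.05), and the pausing list had 3 and 2 of 20. The heterochromatin list had 2 and 1 of 19, the immediate early list 2 and 0 of 33, the histone list 2 and 0 of 68, the protocadherin list 2 and 0 of 53, the markers of other cell types 2 and 1 of 32, the olfactory receptors 1 and 1 of 390, the small nuclear RNA genes 3 and 3 of 42, and the early estrogen-responsive and imprinted genes 0 in both.

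The third comparison asked whether the proteins shared sites. Of the HEXIM1 peaks, those in regions without genes coincided with KAP1 peaks most often. With vehicle 13.6% (13.1 to 14.2) of HEXIM1 peaks overlapped a KAP1 peak, and with estradiol 35.6% (34.3 to 37.0), against at most 0.276% and 0.318% at random. In the gene-free bins the shares were 54.1% (51.7 to 56.5) and 53.8% (51.6 to 55.9), whereas outside them they were 8.35% (7.89 to 8.84) and 22.8% (21.3 to 24.4). At gene boundaries 7.63% (7.00 to 8.30) and 13.1% (11.5 to 14.9) of HEXIM1 peaks overlapped KAP1, and peaks moved to random gene boundaries gave 1.25% and 0.944%. In number, 2024 HEXIM1 peaks overlapped KAP1 with vehicle and 1791 with estradiol, while the HEXIM1 peaks without KAP1 numbered 12809 and 3236. Of the overlapping HEXIM1 peaks 1096 and 674 lay outside the gene-free bins and 928 and 1117 inside. Counted from KAP1, the order differed with vehicle. Then 52.8% (49.6 to 56) of KAP1 boundary peaks overlapped HEXIM1 (at most 11.8% at random boundaries) and 41.0% (39.0 to 43.1) of those in gene-free bins. With estradiol the order was the same as from HEXIM1, with 30% (26.6 to 33.6) and 57.5% (55.3 to 59.8). The 5 highest peaks of each list away from boundaries lay in few places. At 32916440 to 32916686 on chromosome 2, 30.4 kb outside LTBP1, HEXIM1 had 988 normalised tags (964 to 1012) with vehicle and 893.8 with estradiol, and KAP1 1525.5 and 1409.4 in overlapping peaks. At 93470468 to 93470714 on chromosome 3, 402460 bp from PROS1, the values were 244.7, 240.0, 455.7 and 427.8. The others lay on chromosome 4 (from 49709286, 647330 bp from CWH43), on chromosome 5 (from 49601923, 794122 bp from EMB) and on chromosome 18 near LOC124905450 (from 108315). No list of regions that gather tags in any library was used to remove peaks. The heights at these places therefore do not show that both proteins bind there.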

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

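All tests of explanations in this part were chosen after the results were seen, and every comparison between the proteins is untested, with 1 library per condition. The share of HEXIM1 peaks at gene boundaries was lower with estradiol than with vehicle, by a difference of −13.0 percentage points, whereas that of KAP1 was 0.267 points higher. The KAP1 difference lies within the intervals of its shares, and without gene-free bins both shares were higher with estradiol. At shared boundary peaks the median log2 ratio was −0.73 for HEXIM1 and 0.048 for KAP1, opposite in sign, although the KAP1 median became −0.032 when divided by peak width. The difference between the proteins was not tested.

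The lower tags of HEXIM1 at gene boundaries with estradiol were weighed first. One lower enrichment at all boundaries, as a poorer immunoprecipitation gives, keeps stronger peaks more often. The header efficiency (0.30% against 1.22%) is the share of tags in called peaks. A loss of HEXIM1 lowers it too, so it does not by itself show a poorer immunoprecipitation. Of the boundary peaks in neither KAP1 list 13.2% (12.3 to 14.1) were kept below 8-fold and 30.4% (25.4 to 35.8) from 8-fold. Beyond 10-fold the share kept did not rise further, with 26.5% of 68, 25% of 20 and 22.2% of 18 peaks, in wide intervals. An even loss of HEXIM1 with estradiol gives the same rise, so the rise cannot tell these explanations apart with 1 library per condition. At the 97 shared peaks of this kind from 8-fold, the log2 ratios had a standard deviation of 0.67, against 0.29 from counting. These values argue against a single ratio of tags at all strong boundary peaks. At the 715 below 8-fold the deviation was 0.29, against 0.33 from counting, so both remain candidate explanations there. Only peaks called in both lists have a ratio. Wrong labels on the HEXIM1 pair or another library's tags, weighed below, would bear on the boundary peaks too and were not tested there.

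That strong HEXIM1 peaks away from boundaries were seldom called with estradiol is the second pattern. A lower depth is argued against, since the estradiol library held 1.22 times the tags of the vehicle library. One lower enrichment that scales the tags of every peak alike is also argued against. These strong peaks held more tags than boundary peaks of the same fold limit, and yet 4.44% (3.48 to 5.58) were kept, against 30.4% at boundaries. With the peaks in the KAP1 lists the gap was smaller, 25% (23.1 to 26.9) against 37.2% (32.4 to 42.2). In neither KAP1 list, only the weakest peaks, from 4-fold to below 5-fold, showed the opposite order. Of these 12.0% (10.7 to 13.3) were kept away from boundaries against 8.77% (7.68 to 9.95) at boundaries. From 6-fold to below 8-fold the shares were 10.9% (9.14 to 12.9) against 20.1% (17.9 to 22.4), and over all folds 10.6% (9.86 to 11.4) against 14.1% (13.2 to 15.0). With the peaks in the KAP1 lists, they were 25% against 16.8% over all vehicle peaks. The argument is therefore limited to the strong peaks outside the KAP1 lists. They were kept less often than the peaks below 8-fold of the same kind (12.6%, 11.7 to 13.5), whereas one lower enrichment keeps stronger peaks more often. The argument also assumes that the tags at all compared peaks come from the immunoprecipitation. Tags gathered in any library, at boundaries or weaker peaks, would outlast a poorer immunoprecipitation. This case was not tested, so a poorer immunoprecipitation is not excluded. That 29 of the 40 early estrogen-responsive genes (72.5%, and 35% from 15-fold) lie near such a peak may reflect an effect of estradiol on HEXIM1 at sites of the estrogen receptor, and it may as well reflect tags of another immunoprecipitation in the vehicle library or wrong labels on the HEXIM1 pair, as both could place strong peaks near these genes. These explanations cannot be told apart with 1 library per condition, and no motif search was run. The random lists were matched on gene length and not on gene activity, so the excess does not show a preference beyond such activity. Nearness to these genes was also not particular to peaks called only with vehicle. Strong peaks called in both lists lay near 5 of the 40, against a median of 0 in random lists.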

How the results depend on the processing

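No paired analysis was possible because only 1 library per condition was analysed. The search for estrogen response elements, 1 transcription start per gene and lists matched on CpG content were not run. Results counted as stable here if they stayed within the 95% interval of the reported value, and the count of gene lists, which has no interval, if it stayed within 1.5 times. Values below without gene-free bins, without peaks in the other protein's lists, per peak width, and for strong peaks away from boundaries and the genes near them were chosen after the data were seen. All contigs gave the same overlaps, since the lists hold none beyond the chromosomes used. Of the values for the comparisons, 17 were stable in this sense, 74 moved and 1 changed sign; the overlaps with all contigs and the boundary shares of the shorter lists in equal number, which are among the 17, could not change. For every shift the cause was not tested.

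Overlaps are given in the order HEXIM1 vehicle in estradiol, HEXIM1 estradiol in vehicle, KAP1 vehicle in estradiol and KAP1 estradiol in vehicle. They were 17.7%, 52.1%, 43.7% and 61.5% with 50% reciprocal overlap; 24.3%, 71.6%, 48.7% and 68.1% with centres within 1 kb; 24.2%, 24.2%, 58.9% and 58.9% with equal numbers of the strongest peaks; 15.4%, 74.4%, 49.7% and 78.8% at 8-fold; 12.3%, 52.4%, 38.3% and 63.1% without peaks of the other protein; and 14.6%, 64.9%, 39.8% and 60.7% without gene-free bins. Without crowded bins, vehicle peaks gave 17.5% for HEXIM1 and 45.5% for KAP1.

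Boundary shares, in the order HEXIM1 vehicle, HEXIM1 estradiol, KAP1 vehicle and KAP1 estradiol, were 40.1%, 28.0%, 9.17% and 10.1% within 500 bp; 51.1%, 35.0%, 17.4% and 17.1% within 5 kb; 15.7%, 8.20%, 2.86% and 1.44% at 8-fold; 47.1%, 43.4%, 7.00% and 5.78% without peaks of the other protein; and 50.1%, 53.5%, 15.7% and 17.4% without gene-free bins. The strongest vehicle peaks in equal number gave 42.9% and 7.44%.

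The median log2 ratio of HEXIM1 was −0.73 at boundaries, −0.56 in the stronger vehicle peaks (median or above), −0.23 with reciprocal overlap, −0.14 per width, −0.61 without KAP1 peaks and −0.64 without gene-free bins. For KAP1 it was 0.048 at boundaries, opposite in sign to the reported −0.15, and −0.20 in the stronger vehicle peaks, −0.23 per width and −0.094 without gene-free bins.

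HEXIM1 peaks in KAP1 peaks, vehicle then estradiol, were 11.1% and 31.2% with reciprocal overlap, 15.8% and 38.7% with centres within 1 kb, 18.4% and 45.9% away from boundaries, 14.8% and 34.3% in equal number and 8.35% and 22.8% without gene-free bins.

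Strong HEXIM1 peaks away from boundaries were kept in 7.12% from 6-fold, 7.13% from 15-fold, 8.67% from 20-fold and 25% with those in KAP1 lists, and those at boundaries in 37.2% with those in KAP1 lists. Early estrogen-responsive genes near such a peak were 52.5% within 20 kb and 35.0% from 15-fold. Of 44 list and library pairs, 4 lay above the middle 95% of random lists and 10 below, and 5 and 13 within 5 kb. Of 45 further list values, 40 stayed within their limits; within 5 kb, early estrogen-responsive genes with a HEXIM1 vehicle peak rose from 35% to 60% and ribosomal protein genes with a KAP1 vehicle peak from 9.30% to 23.3%. Sites near 4 normalised tags are at the limit of these depths, so that absence from a list is no evidence of absence.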

Other observations

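The tests of explanations in this part were chosen after the results were seen. KAP1 peaks within ribosomal protein genes were called with vehicle and not with estradiol. These genes held 19 separate KAP1 peaks within their bodies with vehicle, with a median of 5.42-fold over the local region, and 0 with estradiol. HEXIM1 had 49 with vehicle and 3 with estradiol in the same genes. Within the 240 chromosome 19 zinc finger genes KAP1 had 18 peaks with vehicle and 11 with estradiol, the highest at 19.9 and 17.9 normalised tags, while HEXIM1 had 89 and 9. The clustered protocadherin genes, which overlap one another, shared 1 KAP1 peak within their bodies with vehicle.

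Of the 70 strong HEXIM1 peaks away from boundaries that were called in both lists, 67 held fewer tags with estradiol, with a median ratio of 0.204. This class was chosen by fold in the vehicle list alone, which by itself favours lower tags with estradiol. The same class of KAP1 had 252 of 284 peaks lower, with a median ratio of 0.793. The 70 HEXIM1 peaks lay within 100 kb of 5 early estrogen-responsive genes, namely ADCY9, FOXC1, GREB1, RET and SMAD7. This compares with a median of 0 in random lists matched on gene length, not on gene activity, and 0.903% of all genes. Strong peaks called in both lists were thus also near these genes more often than near random lists.

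A further pattern is the set of peaks called in all 4 lists, 1186 of the HEXIM1 vehicle list. Of these, 65.8% (63.0 to 68.5) lay in gene-free 1 Mb bins, against 6.85% (6.43 to 7.29) of the other 13647, and their median log2 ratio was −0.082 for HEXIM1 and −0.15 for KAP1. It was −0.046 for HEXIM1 at the 780 in gene-free bins and −0.69 at the 72 at gene boundaries, of which 71 were lower with estradiol. For the peaks in gene-free bins this is consistent with regions that gather tags in any library, and the commands in the headers name no control library. Outside those bins 8.35% of HEXIM1 vehicle peaks still overlapped KAP1, against at most 0.274% at random. This may reflect shared binding, merely open chromatin that both antibodies recover, or regions outside the bins that gather tags in any library. Very high peaks of both proteins did lie outside the gene-free bins. With vehicle, the peak near LTBP1 had 988 normalised tags for HEXIM1 and 1525.5 for KAP1, and that nearest to PROS1 had 244.7 and 455.7. How much of the 8.35% such regions make up was not tested. No value here decides between these explanations.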
